A study of Mus musculus with 8 samples.

How the data were processed

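The series holds 8 arrays, 4 of macrophages from WT hosts and 4 from KO hosts, with genotype and replicate number taken from the sample titles. Per the labels' protocols, total RNA of each sample was amplified and labelled with the dye Cy3. Per the file headers, the authors scanned 1-colour Agilent 4x44K mouse arrays and extracted the spots with Agilent Feature Extraction 10.7.1.1, while the submitters' processing notes name version 10.5. The deposited scanner files give each spot's intensity as a processed signal, already background-corrected by that software per the file headers, together with a median signal, a background signal and marks for spots well above background, saturated or outlying. The headers name the mm9 build, and no coordinates were used from the files.

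The authors also deposited a table of processed intensity values for the same arrays, whose scale is not given in the sources used here. Its columns had medians of 92.0 to 94.0 and one common maximum. Its differences between arrays correlated at 0.9998 with those of the quantile-normalized median signal and at 0.9907 with those of the quantile-normalized processed signal, over 14727 probes. It therefore looks like quantile-normalized median signal without background subtraction, inferred from the values. It served as an alternative only.

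From the scanner files, control spots and outlier-marked spots were left out, spots of a probe were averaged as log2 of the processed signal, and each array's 75th percentile was subtracted. Each array had 45018 spots, 43379 of them not controls, and 0 were saturated. Probes well above background on at least 4 of the 8 arrays were kept (27118 of 41174), and the brightest kept probe stood for its gene, which gave 20851 genes. The files pair a probe with an accession only. Through that accession, without version, 25097 probes were named from a RefSeq table of assembly GRCm38.p6, and 16077 kept their accession. Of the genes tested, 13443 had a symbol.

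The genotypes were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment. The 30 gene lists (16 programmes, 13 cell types and the genes near Atf3) were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, for lists with at least 5 genes tested. Single values were compared by exact permutation, whose smallest p for 4 against 4 is 0.0286. Differences within same-numbered pairs were compared by exact sign flips, whose smallest p for 4 pairs is 0.125. The design, lists, alternatives and the rule for naming genes were fixed before the data were examined. By that rule the text names Atf3, then up to 12 called genes per direction, filled to 6 by smallest unadjusted p where fewer than 6 passed, up to 4 members per programme by smallest p, up to 4 from the called, macrophage, tumour epithelial and T cell marker lists, and the sort markers Adgre1 and Ptprc. Genes outside it are said to be named after their values were seen. Of the members the rule allows, 1 or 2 per programme and 1 to 4 per marker list are given, and the others are not reported here. A group with no array well above background for a probe has only a bound, computed against the lowest signal among probes well above background.

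The labels do not state what the replicate number shares. Deviations from the group means correlated at 0.30, 0.14, 0.70 and 0.51 across genes for the WT and KO samples numbered 1 to 4, all over the 0.1 set as the limit, so the numbers pair the samples in the data. Over the limit too were WT sample 2 with KO sample 4, at 0.15, and WT sample 4 with KO sample 2, at 0.14, so the pair numbered 2 does not stand out. The number took 64.1% of the within-gene sum of squares against 42.9% expected from its degrees of freedom, genotype 10.2% against 14.3%, and slide 14.7% against 14.3%. Numbers 1 and 2 lay on slide 1 and numbers 3 and 4 on slide 2, so the slide's share is part of the number's.

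The gene test was tested on simulated data drawn from the means and spreads of these 20851 genes, with 200 genes changed. For KO against WT it called 14% of 2-fold, 50% of 4-fold, 74% of 8-fold and 76% of 16-fold changes, with 4 false calls. With the hypoxia and glycolysis list shifted by 0.5 on the log2 scale in independently simulated genes, camera called that list and no other. The real programmes had a median estimated correlation of 0.27 between members, so this simulation does not measure false list calls in these data.

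The alternatives were normexp background correction with an offset of 50, quantile normalization, the median of bright probes as scale, no filter and a stricter filter on dim probes, the deposited table, slide as a block and each slide alone, the replicate block, eBayes with trend and robust, array weights, each probe on its own, and each sample left out. Normexp used the median signal, since the mean signal was not a column of the files used here.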

Results

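Gene expression was measured in tumour-associated macrophages, the macrophages that live inside a tumour, taken from breast tumours of C57BL/6 mice. The tumours grew from implanted PyMT cells, a mouse breast cancer line driven by the polyoma middle T oncogene, in hosts that were wild type (WT) or lacked the stress-induced transcription factor ATF3 (KO). Cells positive for both the macrophage surface protein encoded by Adgre1 and CD45, which marks leukocytes, were sorted from the dissociated tumours. The labels give 4 samples per genotype and number them 1 to 4 in each. They do not say whether the samples came from separate mice, so p-values measure only the spread between these samples. Each sample was hybridised to its own 1-colour array, and 2 slides held 4 arrays each, 2 of each genotype. Samples numbered 1 and 2 lay on slide 1 and those numbered 3 and 4 on slide 2. Values within a slide therefore cover only the samples of those numbers. The 75th percentile of the processed signal lay between 619 and 926 intensity units, 20.6 to 31.9 times the local background, and 63.7% to 68.0% of the spots were well above background. The number of arrays limits the precision.

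The comparison asks how the macrophages of ATF3-deficient hosts differ from those of wild-type hosts. Atf3 itself, read by a single probe, was not lower in the samples labelled KO. On the log2 scale relative to each array's 75th percentile, it measured 4.92, 4.99, 4.79 and 4.51 in WT samples 1 to 4 and 5.51, 4.86, 4.96 and 4.88 in KO samples 1 to 4. The group means were 4.80 ± 0.21 in the samples labelled WT and 5.05 ± 0.31 in those labelled KO (SD, n = 4 each), a log2 difference of 0.25 (two-sided exact permutation p = 0.314), or 0.097 without KO sample 1 and 0.15 without WT sample 4. Before scaling, the signals were 18788, 20961, 20177 and 17982 in the samples labelled WT and 29165, 26873, 25495 and 23140 in those labelled KO, so that each of the latter exceeded each of the former (exact permutation p = 0.0286, the smallest that 4 against 4 can give). Unscaled signals keep the brightness of each array. The 75th percentiles were 619, 660, 732 and 788 in WT samples 1 to 4 and 638, 926, 821 and 785 in KO samples 1 to 4. Where the probe lies against the deleted part of the gene is not given in the sources used here. A probe outside that part would check nothing. If the probe lay inside it, the strong signal in all samples labelled KO (4.86 to 5.51) would speak against their labels. Because its place is unknown, the Atf3 signal cannot check the genotype labels either way. Every direction below is between samples labelled KO and samples labelled WT.

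**Figure D1:**
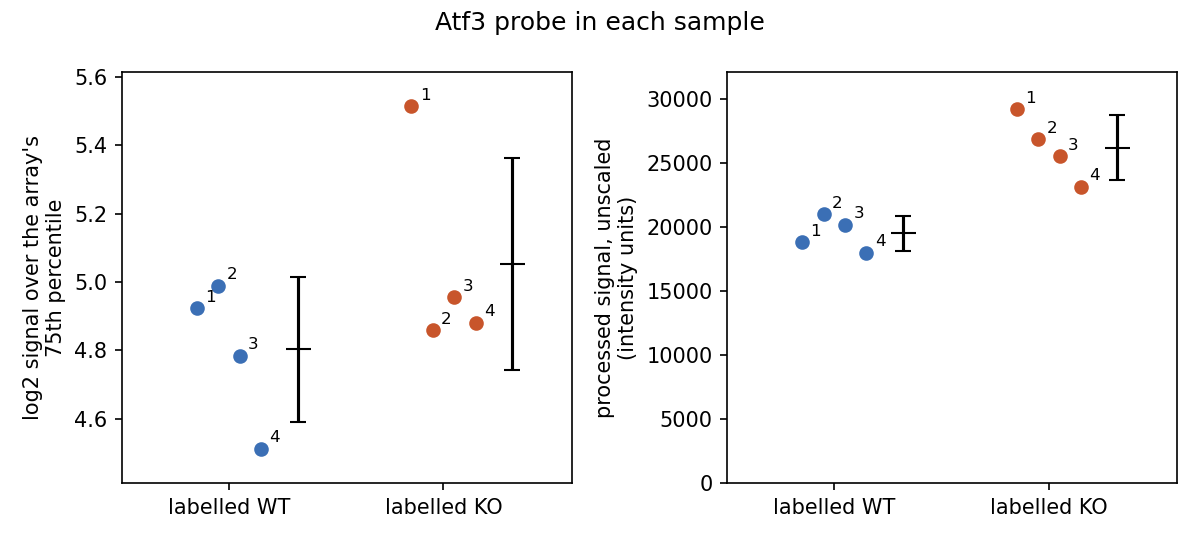
Atf3 signal in each sample, as the log2 value over the array's 75th percentile (left) and as the unscaled processed signal in intensity units (right), with the replicate number beside each point and the group mean ± SD (n = 4) as bars. The scaled values overlap between groups, with means of 4.80 and 5.05. The unscaled signals, which keep the brightness of each array, all lie higher in the samples labelled KO, at 23140 to 29165, than in those labelled WT.

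No single gene was called between the 2 genotypes. Of 20851 genes tested with limma, 0 had an adjusted p under 0.05, with 0 higher and 0 lower in the samples labelled KO, and the smallest adjusted p was 0.412. At an unadjusted p under 0.05 there were 700 genes, 233 higher and 467 lower, where 1043 are expected by chance if all 8 samples are exchangeable. The balance of directions changes with the processing, with 275 higher and 359 lower after quantile normalization, 295 and 317 in the deposited table and 52 and 353 with normexp background correction. The groups did not overlap for 446 genes, 2.14% of those tested, against 2.86% by chance on the same terms, which leave out that the numbers pair the samples. With the replicate number as a block the count of calls was again 0, and 1580 genes had an unadjusted p under 0.05. The median 95% interval of a log2 difference reached 0.744 to either side, and the intervals of 51.5% of the genes excluded a 2-fold change either way.

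The gene with the smallest unadjusted p was Hc, which encodes complement component C5. It measured −2.61 ± 0.20 in the samples labelled WT and −5.02 ± 0.49 in those labelled KO (SD, n = 4 each), a log2 difference of −2.42 with a standard error of 0.27, and each sample labelled KO lay below each labelled WT. Its limma adjusted p was 0.412, and 0.0492 without KO sample 1, the only left-out sample with which any gene was called. The next genes on the lower side did not pass either (limma adjusted p = 0.9999 for each). Their log2 differences were −1.30 for Pcdhb18, a beta protocadherin of a family of similar genes whose probes may not tell members apart, −1.44 for Trim54, a muscle RING-finger protein, −1.33 for Cbx2, a Polycomb protein, and −1.49 for Slc16a8, a monocarboxylate transporter. A second Cbx2 probe gave −0.12. The olfactory receptor gene Olfr410 did not pass either (limma adjusted p = 0.9999) and was not well above background on any array labelled KO. Its mean in the samples labelled WT was 2.55-fold above the bound for those labelled KO, a value without an error.

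On the higher side, none passed, and the smallest unadjusted p values belonged to mostly dim probes. The log2 differences were 0.91 for Npsr1, the neuropeptide S receptor, 2.62 for the cytochrome P450 gene Cyp2f2, 1.20 for a second cytochrome P450 gene, Cyp2b13, 1.77 for Adipoq, the adipocyte hormone adiponectin, 1.96 for the helicase gene Ighmbp2, and 0.64 for Gtf2h5, a subunit of the general transcription factor TFIIH. Of the 4 arrays labelled WT, the probe was well above background on 1 for Cyp2f2, 3 for Cyp2b13, 2 for Adipoq and 1 for Ighmbp2. With normexp background correction the difference turned negative for Npsr1 (−0.31), Cyp2b13 (−0.32), Adipoq (−0.37) and Ighmbp2 (−0.26). That correction also moved the median difference of all genes, from −0.0089 to −0.14, so these sign changes are not particular to the named genes. The other probes of Npsr1, which did not pass the filter on dim probes, gave 0.09 and −0.49.

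Of 30 gene lists, 3 were called by limma camera with its preset correlation, and all 3 mark cell types other than macrophages. T cell markers and markers of NK and cytotoxic cells were higher in the samples labelled KO, and endothelial markers were lower. None of the 3 calls held with a correlation estimated from the data, for which the adjusted p was 0.984 in each case. Other groupings of the same samples called lists as often: 30 of the 35 ways to split the 8 samples into 4 and 4, the real one included, called at least 3 lists. Splits that keep a same-numbered pair together set numbers against each other, which adds to this count. The 7 others that part all same-numbered pairs called 0 to 3. With normexp background correction 14 lists were called at the preset correlation and 0 with an estimated one (smallest adjusted p 0.628). In that setting the median difference of all genes was −0.14, and camera compares a list with the other genes.

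T cell markers had a mean log2 difference of 0.47, with 15 of 17 members higher (limma camera adjusted p = 1.76e-04, and 0.984 with an estimated correlation). Cd247, the zeta chain of the T cell receptor complex, differed by 1.06, the adaptor gene Lat by 0.65 and Cd5 by 0.48, while Cd6 was lower by the probe that stands for it, at −0.62, and higher by a second probe, at 0.41. With normexp background correction Cd5 gave −0.05. No member passed over all genes or adjusted over the list alone. With the replicate number as a block, 4 passed over the list alone (limma adjusted p = 0.0499 for each): Lat and, named after their values were seen, Cd3d at 0.67, Cd3g at 0.51 and Cd8a at 0.51. The list score was higher in the sample labelled KO in 4 of 4 same-numbered pairs, with differences of 1.09, 0.14, 0.26 and 0.40 (exact permutation p over the 8 samples = 0.229). Over the pairs the exact sign-flip p was 0.125, the smallest that 4 pairs can give. The monocyte list, which was not called, was likewise higher in 4 of 4 pairs. Within slide 1 the mean difference was 0.61 and within slide 2 it was 0.33. The call was lost without WT sample 3 (mean difference 0.31, limma camera adjusted p = 0.0818) or without KO sample 2 (0.31 and 0.0573), and the mean difference was 0.75 without WT sample 2.

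Markers of NK and cytotoxic cells had a mean log2 difference of 0.54, with 14 of 16 members higher (limma camera adjusted p = 0.00647, and 0.984 with an estimated correlation). Klrb1c, which encodes the NK1.1 antigen, differed by 1.31 by one probe and by −0.26 by another. The granzyme gene Gzma differed by 1.21, the NK receptor gene Klra8 by 0.91 and Nkg7, a cytotoxic granule gene, by 0.52, and none passed over all genes or adjusted over the list alone. Without WT sample 3 Gzma differed by 0.61, and without KO sample 2 Klra8 differed by 0.34 and Nkg7 by 0.27. The score was higher in 4 of 4 pairs (exact permutation p = 0.343, exact sign-flip p over the pairs = 0.125). Within slide 1 the mean difference was 0.87, and within slide 2 it was 0.21 with the call lost (limma camera adjusted p = 0.437). Without WT sample 3, KO sample 1 or KO sample 2 the mean differences were 0.29, 0.32 and 0.25 and the call was lost (adjusted p = 0.303, 0.118 and 0.637), and without KO sample 3 the mean difference was 0.90. The call was also lost with normexp background correction (0.088 and an adjusted p of 0.108) and with the stricter filter on dim probes (0.050).

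Endothelial markers had a mean log2 difference of −0.98, with 13 of 14 members lower (limma camera adjusted p = 1.76e-04, and 0.984 with an estimated correlation). Tie1, an endothelial receptor kinase, differed by −1.64, Sox17, an endothelial transcription factor, by −2.31, von Willebrand factor (Vwf) by −0.63 and Pecam1, which macrophages express too, by −0.42. None passed over all genes or adjusted over the list alone, and the Sox17 probe was well above background on 3 arrays labelled WT and 1 labelled KO. Sox17 differed by −1.33 without WT sample 4, and its 2 other probes, which did not pass the filter on dim probes, gave −0.54 and −0.11. The score was lower in the sample labelled KO in 4 of 4 pairs, by differences of −1.41, −1.41, −0.10 and −0.98 (exact permutation p = 0.229, exact sign-flip p over the pairs = 0.125). Within slide 1 the mean difference was −1.41, and within slide 2 it was −0.54 with the call lost (limma camera adjusted p = 0.329). Without WT sample 4 the mean difference was −0.59 and the call was lost (0.097).

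**Figure D2:**
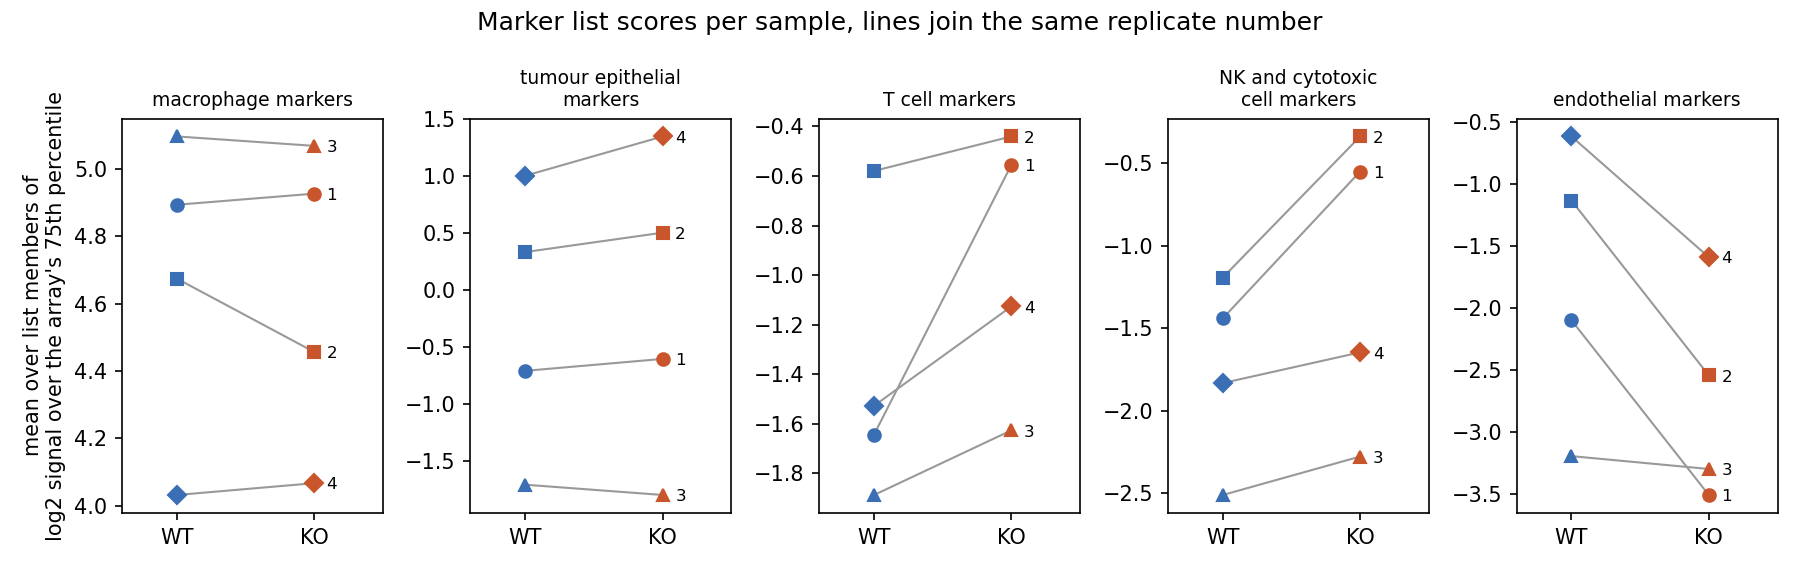
Mean over the members of 5 marker lists of the log2 signal over the array's 75th percentile, per sample, with lines joining samples of the same replicate number (1 to 4, shown at the right of each line) from WT to KO as labelled. Macrophage and tumour epithelial scores differ mainly between numbers. The T cell and NK scores are higher and the endothelial score lower in the sample labelled KO in each of the 4 pairs. Their means per number also range, by 1.25, 1.63 and 2.15, which is more than their largest difference within a pair.

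The 2 interferon lists just missed the threshold at the preset correlation. Genes of the type I interferon response were higher by 0.15 on average, with 20 of 27 members higher, and genes of the interferon gamma response and antigen presentation by 0.18, with 20 of 24 higher (limma camera adjusted p = 0.0518 for each). With an estimated correlation the limma camera adjusted p was 0.984 for each. Both scores were higher in the sample labelled KO in 3 of 4 pairs (exact permutation p = 0.6 and 0.657). Over the left-out samples the first mean ranged from 0.012, without WT sample 4, to 0.25, without KO sample 4. The second ranged from −0.070, without WT sample 4, to 0.32, without WT sample 1, and was −0.015 within slide 1. Ifi44 differed by 1.06 and Usp18, an interferon-induced protease, by 0.40. In the second list Tap2, a peptide transporter of antigen presentation, differed by 0.39 and the chemokine gene Cxcl9 by 0.73, or 0.19 without WT sample 4. With the replicate number as a block, the preset correlation called both interferon lists (adjusted p = 0.00440 and 0.00449) and monocyte markers (0.00677) beside the T cell, NK and endothelial lists, 6 in all. With an estimated correlation the blocked fit called 0, and the adjusted p was 0.717 for type I interferon, 0.951 for interferon gamma, 0.951 for monocyte markers, 0.717 for T cell and for NK markers and 0.796 for endothelial markers.

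The remaining programmes were not called, and their members went both ways. Among inflammatory cytokines and chemokines, 13 of 23 genes were higher (adjusted p = 0.948), with Il6 at 0.42 and Tnf at −0.43. Alternative activation genes had 15 of 23 higher (0.544), with the macrophage lectin gene Mgl2 at 0.69 (0.10 without WT sample 4) and Il10 at −0.43 (−0.06 without WT sample 2). Matrix remodelling genes had 18 of 31 lower (0.924), among them fibronectin (Fn1) at −0.43 and the urokinase gene Plau at −0.59. TGF-beta signalling genes had 15 of 25 lower (0.948), with Tgfb3 at −0.37 and endoglin (Eng) at −0.26, and angiogenesis genes had 16 of 22 lower (0.544), with Pdgfb at −0.49 and Vegfb at −0.30, the latter at −0.0006 by its other probe. Integrated stress response genes, a programme in which ATF3 takes part, had 12 of 19 lower (0.948), with Sesn2 and the serine synthesis gene Phgdh both at −0.28, though 2 other Phgdh probes gave 0.14. Immediate early and AP-1 genes had 20 of 27 lower (0.902), with Klf4 at −0.22 and Klf2 at −0.15.

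Metabolic and stress programmes were likewise not called. Hypoxia and glycolysis genes had 23 of 31 lower (adjusted p = 0.544), with the collagen hydroxylase gene P4ha1 at −0.23 and Hif1a at 0.17. Sterol synthesis genes had 14 of 21 lower (0.959). In that list Insig1, a sterol sensor, differed by −0.77 by one probe and 0.57 by another. Lipid handling and foam cell genes had 17 of 26 lower (0.948), with the apolipoprotein gene Apoc1 at 0.85 and the cholesterol exporter gene Npc1 at −0.34. Oxidative stress genes were split evenly, with 12 of 24 higher (0.948), Gclc, of glutathione synthesis, at −0.39 and Blvrb, a biliverdin reductase, at 0.42. Heat shock genes had 10 of 16 lower (0.948), with Chordc1 at 0.28 and Hsf1 at −0.30. Cell cycle genes had 22 of 38 lower (0.948), with the replication licensing gene Cdt1 at 0.44 and Ccne1 at 0.49, the latter at −0.02 by its other probe. Genes of apoptosis and p53 targets had 13 of 23 lower (0.948), with Bid at 0.32. Mean and median differed in sign for TGF-beta signalling, cell cycle, B cell and fibroblast lists, and the camera direction opposed both for sterol synthesis and heat shock.

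The macrophage genes of the sorted cells were not called. Macrophage markers had a mean log2 difference of −0.04, with 13 of 17 members lower (limma camera adjusted p = 0.948). The sort marker gene Adgre1 measured 4.14 ± 0.60 and 4.07 ± 0.54 and the CD45 gene Ptprc 4.52 ± 0.54 and 4.42 ± 0.55 in the samples labelled WT and KO (SD, n = 4 each), while 2 other Ptprc probes gave differences of 0.19 and 0.02. Fcgr1, a high-affinity IgG receptor, differed by 0.19. Tumour epithelial markers had 14 of 23 higher (0.902), with the milk protein gene Wap at 0.84 and Tspan8 at 1.12, with standard errors of 0.90 and 1.52. The other marker lists were not called: monocyte (adjusted p = 0.276), dendritic cell (0.902), neutrophil (0.948), eosinophil and mast cell (0.948), B cell (0.948), fibroblast (0.948), erythroid (0.935) and adipocyte (0.935). Adjusted over each of the 30 lists alone, Adipoq among the adipocyte genes was the only member that passed (limma adjusted p = 0.0222, and 0.0771 with the replicate block). With the replicate block the dendritic cell gene Batf3, named after its value was seen, passed at a log2 difference of −0.83 (0.0351), besides the 4 T cell genes above.

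A targeted allele can carry neighbouring sequence of another strain, so genes near Atf3 were tested as a list. The 62 tested genes within 10 Mb of Atf3, taken from the GRCm38.p6 assembly, had a mean log2 difference of −0.04, with 30 higher and 32 lower (limma camera adjusted p = 0.948), and none reached an unadjusted p under 0.05. With the replicate number as a block 5 of the 62 did, a share near that of all genes tested (1580 of 20851). Named after their values were seen, they were Batf3, the dendritic cell gene above, Ints7, Cr1l, Lamb3 and Hhat, with log2 differences of −0.83, 0.64, 0.34, −0.40 and −0.47. The mixed test of fry, which counts changes in either direction, gave the list an adjusted p of 0.951, and 0.34 with the block. None passed adjusted over these 62 genes (the smallest limma adjusted p was 0.168, for Batf3).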

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

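The tests of the explanations below, other than the counts over the 35 splits of the samples and of lists with the replicate block, were chosen only after the result was seen. In 188 groups of 4 samples (64 genes and 30 lists, under each label) 8 held a sample far from the other 3, where chance gives about 9. The values were Atf3 in KO sample 1 at 5.51, the inflammatory cytokine and chemokine score in KO sample 1 at 2.95, the alternative activation score in WT sample 4 at 0.66 and the erythroid score in WT sample 2 at −0.23. Among the named genes they were Cyp2f2 in WT sample 4 at −4.60 and in KO sample 3 at −4.94, Hc in KO sample 1 at −4.29 and Sox17 in KO sample 4 at −4.40. All are log2 values over the array's 75th percentile.

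Samples of the same number deviated together, least so for number 2. Numbers 1 and 2 lay on slide 1 and numbers 3 and 4 on slide 2, so the slide's share is part of the number's. The slide as the whole cause is argued against by that share, 14.7% of the sum of squares against 14.3% expected. A varying share of tumour epithelial and stromal cells may account for the shared deviations. Numbers 3 and 4 have the lowest and highest epithelial scores. From number 3 to number 4 the tumour epithelial score rose by 2.92 and the fibroblast score by 1.96, while the macrophage score fell by 1.03. Within a pair the epithelial score differed by 0.34 at most. Between these extremes the epithelial score rose by 2.49 more than the T cell score. They are extremes of the epithelial score itself. The contrast therefore cannot decide, over all numbers, on a smaller macrophage share that lifts all other cells alike. Krt18, named after its values were seen, ranged from 2.22 to 5.06 over the samples, the sort on the Adgre1 protein and CD45 should remove such cells, and no biological explanation was tested, since the labels do not say what a number stands for.

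T cell and NK markers were higher and endothelial markers lower in the samples labelled KO, by calls that were lost with an estimated correlation (limma camera adjusted p = 0.984 for each, and 0.717, 0.717 and 0.796 with the replicate block). A lower macrophage share under that label would move both kinds of list alike, while the T cell and endothelial shifts differed by 1.45 on average over the 4 pairs (SD 0.875), in the same direction in each. These lists were picked for calls in opposite directions, so the difference restates the pattern and cannot decide on that explanation. Shares of T cells and endothelial cells that vary between samples are candidate sources. Within groups, T cell genes correlated at 0.557 and endothelial genes at 0.502, against a median of 0.27 over the 16 programmes. Among those programmes, interferon gamma and antigen presentation gave 0.78 and cell cycle 0.54, the others less than either list, and macrophage markers gave 0.90. A high correlation therefore does not single out a varying cell share. Cd8a ranged from 0.68 to 2.99 and Cdh5 from −1.16 to 1.82 over the samples, both named after their values were seen, though the sort should remove cells without the Adgre1 protein. Chance stays open. Of all 35 splits of the samples, 30 called at least the 3 lists observed, up to 16. Splits that keep a pair together set numbers against each other, so that count does not measure chance for a split that parts all pairs. The 7 others that part all pairs called 0 to 3 lists. With the replicate block 2 of the 8 splits that part all pairs called at least the 6 observed, up to 8. These 8 splits are too few for a share under 0.05. A difference due to the hosts' genotype stays open and untested beyond this.

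Atf3 was not lower in the samples labelled KO. RNA of the implanted tumour cells, which carry their own Atf3, is argued against as the sole source. Atf3 spanned 0.65 over the 4 samples labelled KO while their epithelial score spanned 3.14. This takes the Atf3 RNA of a tumour cell as constant, and a part of the signal from tumour cells stays open. A swap between groups cannot be told apart from correct labels, because every sample labelled WT had a strong signal (4.51 or more), which a probe outside the deleted part gives either way. A probe outside the deleted part likewise cannot be told apart from RNA that the targeted allele still makes (log2 difference 0.25), since the sources do not place the probe.

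Over all 35 splits, chance cannot be excluded either for the 700 genes at an unadjusted p under 0.05, since 21 of 35 splits gave as many and the highest other gave 5247. For an adjusted p under 0.05 the splits decide nothing, because each of the 35 gives at least the 0 genes observed, and the highest other gave 1243. Splits that keep pairs together set numbers against each other, and among the 8 that part all pairs only 1, the real one, gave as many as the 700, where the highest other gave 447. With the replicate block the real split again gave the most of these 8 at an unadjusted p under 0.05, 1580 against 1040 in the highest other, and all 8 called 0 genes at an adjusted p under 0.05. These 8 splits are too few for a share under 0.05. The split with 1243 genes set numbers 1 and 3 against numbers 2 and 4, which points to the structure of the samples by number. The split that follows the slides called 1 gene and 14 lists.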

How the results depend on the processing

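The gene count stayed at 0 in every alternative except leaving out KO sample 1 (0 to 1 genes, and 0 to 1 lower, over the left-out samples; limma adjusted p of Hc 0.0492). With 8 arrays at a signal of 20.6 to 31.9 times background, 50% of 4-fold and 74% of 8-fold simulated changes were called, so that changes of this size can be missed. The number of called lists was 3, and 14 with normexp, 5 without a filter, 5 with slide as a block, 6 with the replicate block, 5 with each probe on its own, 1 to 7 over the left-out samples (1 without WT sample 3 or KO sample 2) and 0 with an estimated correlation or fry. Among alternatives chosen after seeing the data, it was 5 with the tumour epithelial score as a covariate, 6 with the replicate block plus trend and robust, 0 with the replicate block under an estimated correlation or the directional test of fry (its mixed test with the block called type I interferon, adjusted p = 0.00558, and T cell markers, 0.0282), and 3 without number 4 of both groups. Adjusted over the list alone, the replicate block added Lat, Cd3d, Cd3g, Cd8a and Batf3 and lost Adipoq, and beyond these and the 3 lists it added it changed no other call. Atf3 kept its direction throughout, with a log2 difference of 0.097 to 0.31 over the left-out samples, lowest without KO sample 1 and at 0.15 without WT sample 4. Normexp moved the median difference of all genes from −0.0089 to −0.14. The cause of the changes below was not tested. Each sign change is of a value that was not called before, and the adjusted p stands beside those that are called in the new direction.

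With normexp, the differences became −0.31 for Npsr1, −0.32 for Cyp2b13, −0.37 for Adipoq, −0.26 for Ighmbp2, −0.048 for Cd5, 0.012 for Adgre1, 0.092 for Ptprc and 0.066 for Klf2. The list means became −0.0010 for TGF-beta signalling, 0.047 for hypoxia (limma camera adjusted p = 0.00937), 0.049 for lipid handling (0.0343), 0.086 for immediate early genes (0.00250), −0.012 for cell cycle, 0.11 for heat shock (0.00562), 0.033 for apoptosis (0.0249), 0.13 for macrophage (0.00562), −0.074 for dendritic cell, −0.048 for epithelial, −0.034 for fibroblast and −0.36 for adipocyte markers. On slide 2 alone they were 0.054 for Adgre1, 0.031 for Tgfb3, −0.027 for Hif1a, −0.057 for TGF-beta signalling, 0.0033 for macrophage and 0.067 for B cell markers. On slide 1 alone they were −0.14 for cytokines, −0.015 for interferon gamma, −0.0014 for cell cycle, 0.015 for apoptosis and −0.045 for fibroblast markers. Array weights gave −0.053 for cytokines, 0.035 for sterol synthesis, −0.0053 for oxidative stress, 0.017 for apoptosis and −0.052 for eosinophil markers. Each probe on its own gave −0.0013 for TGF-beta signalling, −0.015 for cell cycle, 0.0096 for heat shock and −0.045 for fibroblast markers. The stricter filter gave −0.028 for TGF-beta signalling and 0.24 for B cell markers, and the values of the deposited table gave 0.0086 for apoptosis and −0.013 for fibroblast markers. The epithelial covariate gave −0.026 for TGF-beta signalling, 0.00043 for macrophage and −0.080 for fibroblast markers. Without number 4, cytokines gave −0.047, cell cycle −0.037, apoptosis 0.017 and fibroblast markers −0.039.

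Over the left-out samples, Adgre1 ranged from −0.34 to 0.12, Ptprc from −0.34 to 0.15, Fcgr1 from −0.17 to 0.38 and Tspan8 from −0.11 to 2.44. Other named genes that moved by over 1.5 times without a change of sign were Cd5 (0.29 to 0.59), Cd3g (0.28 to 0.77), Cd8a (0.20 to 0.83), Gzma (0.61 to 1.64), Nkg7 (0.27 to 0.79), Klra8 (0.34 to 1.47), Pecam1 (−0.53 to −0.28), Sox17 (−3.38 to −1.33), Wap (0.14 to 1.45), Tap2 (0.25 to 0.52), Cxcl9 (0.19 to 1.00), Npc1 (−0.49 to −0.21), Mgl2 (0.10 to 0.97), Il10 (−0.78 to −0.06), Sesn2 (−0.42 to −0.14), Phgdh (−0.44 to −0.018), Il6 (0.18 to 0.57), Tnf (−0.71 to −0.14), Tgfb3 (−0.49 to −0.20), P4ha1 (−0.32 to −0.14), Klf4 (−0.33 to −0.14), Cdt1 (0.29 to 0.57), Ccne1 (0.32 to 0.81), Blvrb (0.27 to 0.55), Chordc1 (0.17 to 0.41), Hsf1 (−0.50 to −0.15), Bid (0.19 to 0.46) and Batf3 (−1.16 to −0.48). Other probes of a named gene that moved it by over 1.5 times on the same side gave 0.66 for Chordc1, −0.65 for Hsf1, −0.79 for Fn1, −0.25 for Klf2 and −0.27 for Pdgfb, and 0.48 for Cyp2b13 by a probe that did not pass the filter. Programme means ranged from −0.17 to 0.092 for the integrated stress response, −0.19 to 0.13 for cytokines, −0.070 to 0.32 for interferon gamma, −0.080 to 0.40 for alternative activation, −0.11 to 0.032 for matrix remodelling, −0.15 to 0.14 for TGF-beta signalling, −0.34 to 0.045 for angiogenesis, −0.16 to 0.12 for sterol synthesis, −0.16 to −0.014 for hypoxia, −0.11 to 0.052 for lipid handling, −0.15 to 0.041 for immediate early genes, −0.15 to 0.18 for cell cycle, −0.041 to 0.060 for oxidative stress, −0.069 to 0.032 for heat shock and −0.082 to 0.053 for apoptosis. Marker means ranged from −0.26 to 0.14 for macrophage, −0.12 to 0.55 for monocyte, −0.052 to 0.45 for dendritic cell, −0.63 to 0.38 for neutrophil, −0.25 to 0.87 for eosinophil and mast cell, −0.30 to 0.27 for B cell, −0.36 to 0.68 for epithelial, −0.34 to 0.34 for fibroblast, −0.51 to 0.059 for erythroid and −0.022 to 0.24 for adipocyte lists. Genes near Atf3 ranged from −0.13 to 0.058.

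Lists not called before were also called without a change of sign. All calls of lists in this part rest on the preset correlation. With a correlation estimated in each of these settings, chosen after seeing the data, 0 lists were called in any, and the smallest adjusted p was 0.628, with normexp. At the preset correlation and with normexp these were cytokines (limma camera adjusted p = 0.0145), type I interferon (2.73e-06), interferon gamma (1.43e-09), alternative activation (0.00103), oxidative stress (9.66e-04) and monocyte markers (0.00370). Over the left-out samples they were type I interferon without WT sample 1 or 2 or KO sample 3 or 4 (5.04e-04, 0.00311, 0.0148 and 0.00124), interferon gamma without WT sample 1 or 2 or KO sample 4 (3.27e-04, 0.00773 and 8.42e-04) and monocyte markers without WT sample 1 or KO sample 4 (3.27e-04 and 0.0117). Without KO sample 4 alternative activation was called (0.0176), without KO sample 1 cell cycle (0.00310), without WT sample 4 macrophage markers on the lower side (0.0301), and without WT sample 4 or KO sample 3 tumour epithelial markers on the higher side (0.0434 and 0.00250). Type I interferon was also called on slide 2 alone (0.0339), with slide as a block (0.0207), without a filter (0.0479), with each probe on its own (0.0165) and with the epithelial covariate (0.0276), interferon gamma in the same 5 settings (0.00177, 0.0290, 0.0479, 0.0156 and 0.0129) and with the deposited table (0.00918), and monocyte markers on slide 2 alone (0.00387).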

Other observations

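Scores of tumour epithelial, fibroblast and neutrophil markers ranged over the replicate numbers by 2.92, 1.96 and 2.76 and differed within a pair by 0.34, 0.49 and 0.34 at most, in a comparison chosen after seeing the data. A limma test of the number beside genotype called 1511 of 20851 genes (7.25%), among them 13 of 23 tumour epithelial, 9 of 16 neutrophil, 6 of 15 monocyte, 7 of 23 alternative activation, 4 of 19 fibroblast, 2 of 17 macrophage, 2 of 14 endothelial and 0 of 24 interferon gamma and antigen presentation genes. No test compared the lists with each other. The mean epithelial score of the WT and KO sample was −0.65, 0.42, −1.75 and 1.18 for numbers 1 to 4, and the fibroblast score 0.64, 0.87, −0.27 and 1.69. Macrophage scores ran the other way, at 4.91, 4.57, 5.08 and 4.05. The keratin gene Krt8, named after its values were seen, measured 3.39, 4.43, 1.58 and 4.93, and the epithelial adhesion gene Epcam 1.68, 2.68, −0.06 and 3.30 (limma adjusted p of the number = 0.0157 for each).

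Scores of the other leukocytes did not share 1 order over the numbers. Monocyte scores were 2.46, 1.66, 1.56 and 0.79 for numbers 1 to 4. Number 1 had the highest neutrophil score, 1.16 against −0.33, −1.60 and −0.25 in numbers 2 to 4, and the highest eosinophil and mast cell score, −0.02 against −1.49 in number 2 and −2.23 in number 4, with number 3 lowest. The neutrophil calprotectin genes S100a8 and S100a9, also named after the fact, measured 3.58 and 4.99 in number 1 and −0.17 and 1.72 in number 3 (limma adjusted p = 0.0157 for each). T cell, NK and B cell scores were highest in number 2, at −0.51, −0.77 and −1.43, and lowest in number 3, at −1.76, −2.39 and −2.75. Dendritic cell scores were −0.23, −0.32, −1.41 and −1.39 for numbers 1 to 4.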
